A study of Mus musculus with 16 samples.

How the data were processed

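The samples were T cells sorted as CD45+ TCRβ+ from tumours of mice bearing MOC1, a transplantable mouse oral cancer line. Tumours of 5 mice were processed according to the series record, and the cells of each treatment were pooled. The 4 treatments were control, anti-PD-L1, anti-TGF-β and bintrafusp alfa, an antibody against PD-L1 fused to a trap made of the TGF-β receptor II ectodomain. Each pool was loaded into 2 captures of a droplet 5′ single-cell RNA kit with a target of 10000 cells each, named flow cell 1 and flow cell 2 in the labels. The captures of a treatment therefore share their cells' source, so every p-value here measures the spread between captures, which may be technical, and not the spread between mice. Control flow cell 2 has bintrafusp control in its title but a control label, and was used as control.

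The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.0.1 and restricted to barcodes called as cells. The authors' clonotype tables hold cell barcode counts and fractions per clonotype, and CDR3 sequences. Tables of 6 captures were used: both of bintrafusp alfa, both of anti-PD-L1, control flow cell 2 and anti-TGF-β flow cell 1. Those of the other captures were not analysed here. The sources used here give no genome build or annotation, so no coordinates are printed.

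Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs, unless Scrublet (in scanpy 1.11.5), run per capture, called them doublets. Its automatic threshold called 20 cells in all, too few for an experiment of this size, so doublets are in effect still present. Of 40165 barcodes, 39749 were retained. Counts per 10000 were log-transformed, and 2000 variable genes were chosen without receptor, immunoglobulin, ribosomal protein and mitochondrial genes. With 30 principal components and 15 neighbours, Leiden clustering (leidenalg 0.10.2) at resolution 1.0 gave 23 clusters, with no integration of captures. Classes were named from 168 markers fixed before the data were examined, 2 of which are not in the files' 32285 genes. A cluster took a class whose markers led or tied, by fold against cells outside that class. Naive markers tied in clusters 6 and 8. Judged against all other cells, clusters 2, 5, 6 and 8 are led by other genes, and the choice of reference was made after the clusters had been seen.

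UMI counts were summed over the cells of a class in each capture. Genes were kept by edgeR's filterByExpr, with a minimum count of 10 and a minimum total of 15, and normalised by TMM. edgeR 4.0.16 quasi-likelihood F-tests were run on all 8 captures in 1 fit per class, with Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts were each treatment against control, bintrafusp alfa against each single antibody, and additivity in CD8-like cells (bintrafusp alfa minus both antibodies plus control, on the log scale). Log2 fold changes carry standard errors (SE), and CPM values are means of 2 captures with their SD. They use TMM-scaled library sizes, and unscaled ones where Foxp3 or Cd8a stands for the make-up of a class. A class by treatment term tested whether CD8-like and regulatory T-like cells differed in their response. On simulated data in which 200 genes were changed, the share recovered for bintrafusp alfa at folds of 1.25, 1.5, 2 and 4 was 52%, 86%, 82% and 98% in CD8-like cells. It was 10%, 34%, 66% and 88% in conventional CD4-like cells, and 6%, 28%, 62% and 82% in regulatory T-like cells.

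Gene lists, 32 in all and fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted within a class and comparison, and again with an estimated correlation. They were cytotoxic effector, inhibitory receptor and exhaustion, naive and memory progenitor, TGF-β target, tissue residency, tissue egress and circulation, type I interferon response, interferon gamma response, antigen processing and MHC class I, S phase, G2 and M phase, glycolysis, oxidative phosphorylation, cholesterol synthesis, NF-kB and costimulation, cytokines and chemokines, chemokine receptors, regulatory T cell, T helper 17, T follicular helper, immediate early and dissociation stress, mitochondrial transcripts, and cytosolic ribosomal protein. The other 9 hold markers of macrophages, dendritic cells, neutrophils, B cells, NK cells, fibroblasts, endothelium, epithelial or tumour cells, and erythroid cells. Members are counted by the test over all genes, and again adjusted over the list alone. Lists with fewer than 3 tested members in a class have no result there.

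Named genes follow a rule fixed before the data were examined. In CD8-like cells these are the 8 genes with the largest rise and the 8 with the largest fall against control, with adjusted p under 0.05, mean CPM of at least 20, and both treated captures beyond both control captures. In the other classes and contrasts the first 5 each way were taken. Up to 4 members of each list were eligible as examples by the same limits, and those printed were picked from them after their values had been seen. Pdcd1, Cd274, Tgfb1, Tgfbr2, Smad7, Itgae, Tcf7, Foxp3, Gzmb and Ifng, 10 genes, were always eligible. Def8, and Cdk5rap1 outside its largest changes, were chosen after their values had been seen. The results of 1 gene that met these rules are not reported here.

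Class shares are percentages of retained cells, and differences among the 4 groups were tested by exact permutation over the 105 arrangements of 8 captures, where the smallest possible p is 0.0095. Arranged within flow cells there are 24, with a smallest p of 0.0417. A comparison of 2 captures with 2 cannot go below 0.333, so no share is tested pairwise. Clonotype shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Clonality is 1 minus normalised Shannon entropy. Tables were also thinned to the smallest table's 3554 cells in 1000 draws, and overlap is given as the Morisita-Horn index with its SD over 500 redraws of cells. TCR β V segment usage is the share of Trbv UMIs in CD8-like cells, with the effective number of segments as the exponential of the Shannon entropy.

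Alternatives were DESeq2 1.42.0 size factors and Wald test, no expression filter, a stricter cell filter (1000 genes, 5% mitochondrial), a gate per cell on Cd4, Cd8a, Cd8b1 and Foxp3 UMIs, thinning cells to 3000 UMIs, resolutions 0.5 and 2.0, doublets kept, each capture left out in turn, and the flow cell as a replicate block. Thinning left out the shallower cells, 3154 of 12506 in control, 515 of 9410 with anti-PD-L1, 1159 of 8571 with anti-TGF-β and 389 of 9262 with bintrafusp alfa, so it is also an unequal cell filter. Added after seeing the data were leaving out the 5% of cells with the highest doublet scores and testing each CD8-like cluster of at least 400 cells alone. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3, with random seed 1.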

Results

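Single T cells of 4 treatments were measured, with 2 captures each. Control captures held 5360 and 7297 cell barcodes with 35555380 and 36852275 UMIs. Anti-PD-L1 captures held 4807 and 4678 barcodes with 42871122 and 42291009 UMIs, and anti-TGF-β captures held 4401 and 4255 barcodes with 34046779 and 34809183 UMIs. Bintrafusp alfa captures held 4532 and 4835 barcodes with 53989419 and 53968366 UMIs. The median was 5285.5 and 3975 UMIs per barcode in control, 7557 and 7787 with anti-PD-L1, 5636 and 5968 with anti-TGF-β, and 9749 and 9270 with bintrafusp alfa.

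T cell class shares were compared first. CD8-like cells, which carry Cd8a (clusters 1, 2, 3, 5, 6 and 20), made up 65.0% ± 0.048 of retained cells with bintrafusp alfa (SD, n = 2), against 36.4% ± 0.762 in control, 43.5% ± 0.70 with anti-PD-L1 and 25.8% ± 0.826 with anti-TGF-β. Regulatory T-like cells, led by Foxp3, the lineage factor of suppressive CD4 cells (cluster 0), made up 2.64% ± 0.062 with bintrafusp alfa, 22.2% ± 0.804 in control, 16.6% ± 0.587 with anti-PD-L1 and 27.8% ± 0.94 with anti-TGF-β. Conventional CD4-like cells, led by Cd40lg, Il13 and Cd4 (clusters 7 and 8), made up 6.63% ± 0.188 with bintrafusp alfa, 13.3% ± 0.642 in control, 12.2% ± 0.414 with anti-PD-L1 and 10.5% ± 0.944 with anti-TGF-β. NK or NKT-like cells made up 8.65% in control, 6.92% with anti-PD-L1, 8.36% with anti-TGF-β and 3.45% with bintrafusp alfa. Naive or central memory-like cells made up 1.71%, 1.15%, 2.63% and 1.046% in the same order.

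For these 5 classes the exact permutation p over all arrangements was 0.0095, the smallest possible, with an adjusted p of 0.0209 over 11 classes. Within flow cells it was 0.0417, also the smallest possible. Cycling-like cells made up 6.85% in control, 5.42% with anti-PD-L1, 7.02% with anti-TGF-β and 11.1% with bintrafusp alfa, with an exact permutation p of 0.019 (adjusted 0.0348). Interferon-high-like cells, led by Ifit3, Ifit1 and Isg15, made up 1.76%, 4.94%, 1.76% and 2.44% in that order, and cells of no named class 8.05%, 8.06%, 14.7% and 6.62%. Each had an exact permutation p of 0.0286 (adjusted 0.0393). Within flow cells the exact permutation p was 0.0833 for these 3 classes. Macrophage or monocyte-like cells lay between 0.722% and 0.935%, neutrophil-like cells between 0.265% and 0.628%, and epithelial or tumour-like cells numbered 21, with exact permutation p of 0.257, 0.419 and 0.676. With the gate per cell, the anti-PD-L1 difference from control turned to 1.97 percentage points for regulatory T-like and 1.85 for conventional CD4-like cells. Classes differed within as well: cluster 2 was 55.6% of CD8-like cells with bintrafusp alfa, 16.1% with anti-PD-L1, 5.16% with anti-TGF-β and 0.83% (38 cells) in control, while cluster 6 was 2.24%, 10.3%, 25.3% and 33.6%.

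**Figure D1:**
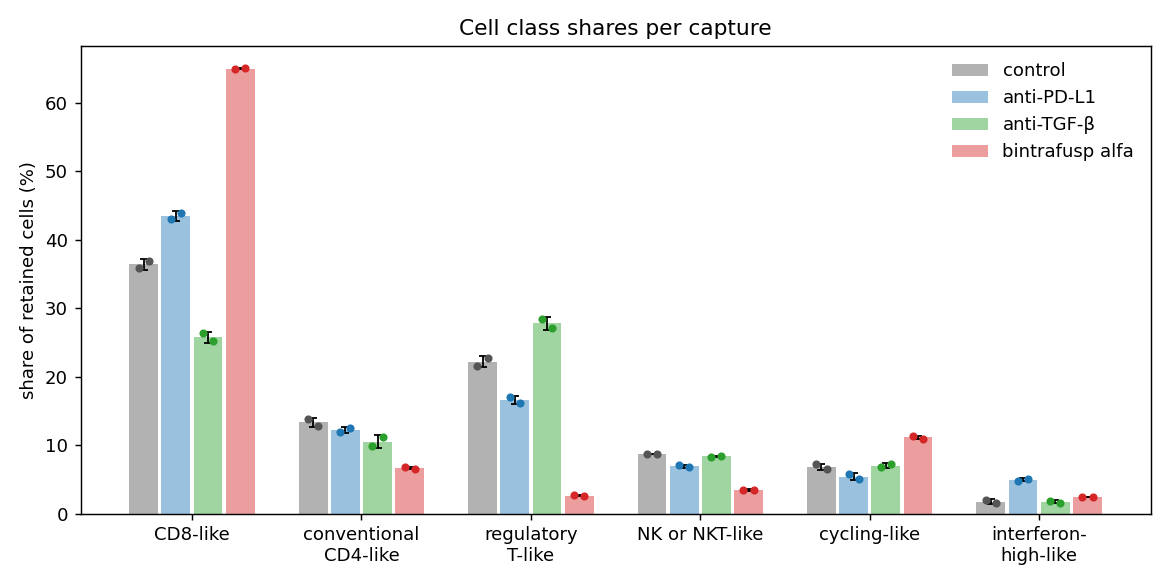
Share of retained cells (%, vertical axis) in 6 cell classes (horizontal axis) for the 4 treatments; bars are means of 2 captures, points are single captures and error bars are SD. CD8-like cells reach 65.0% and regulatory T-like cells 2.64% with bintrafusp alfa, against 36.4% and 22.2% in control.

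CD8-like cells under bintrafusp alfa were compared with control. The genes that rose the most were led by Ccr2, a chemokine receptor of cells recruited from blood, at 77.9 ± 0.353 against 9.79 ± 0.397 CPM (SD, n = 2), a log2 fold change of 2.99 ± 0.078 (SE). Serpine2 (2.34 ± 0.094), a protease inhibitor, Gbp6 (2.03 ± 0.081), an interferon-induced GTPase, Il12rb2 (2.03 ± 0.061), a chain of the IL-12 receptor, and Lmna (1.94 ± 0.082), a nuclear lamin, followed, with Setbp1 (1.92 ± 0.068), Fosb (1.92 ± 0.062) and Egr1 (1.91 ± 0.066), of which the last pair are immediate early transcription factors. The largest falls were in Xcl1, a chemokine that draws cross-presenting dendritic cells, at 36.5 ± 3.9 against 582 ± 0.0498 CPM (SD, n = 2), a log2 fold change of -3.996 ± 0.094, and in Cd83 (-3.94 ± 0.13), an activation marker. Ccr7 (-3.35 ± 0.10), the lymph node homing receptor, Penk (-3.31 ± 0.068), which encodes proenkephalin, Timp2 (-3.16 ± 0.075), a metalloproteinase inhibitor, Ccl1 (-3.13 ± 0.28), a chemokine, Car2 (-2.97 ± 0.062), a carbonic anhydrase, and Igfbp7 (-2.66 ± 0.095) also fell. Ccr2, Ccr7, Penk and Ccl1 turned in 1 or 2 clusters. Here and below, genes that turned in clusters took the other sign in some of the 5 clusters tested alone. They did so without passing unless a value past the edgeR threshold is given beside them. Values of every cluster, passing or not, stand in the section on processing.

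In all, 4049 of 12712 genes tested rose and 3809 fell, by edgeR at an adjusted p under 0.05. Ccr7 leads cluster 6, and Serpine2 and Setbp1 lead cluster 3. Shares of these clusters differed between groups. Within single CD8-like clusters 173 to 3299 genes changed.

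Of the interferon gamma response genes, 16 of 21 rose and 2 fell (camera adjusted p = 1.98e-05, adjusted p = 0.501 with an estimated correlation). Here and below, where no counts adjusted over the list alone are printed, these were the same. Of the type I interferon response genes, 15 of 23 rose and 3 fell (camera adjusted p = 0.0339) and of the oxidative phosphorylation genes, 0 of 32 rose and 30 fell (camera adjusted p = 7.1e-11), with adjusted p = 0.592 and 0.501 with an estimated correlation. Of the cholesterol synthesis genes, 0 of 19 rose and 16 fell (camera adjusted p = 0.000254) and of the cytokines and chemokines, 3 of 22 rose and 14 fell (camera adjusted p = 0.0473), with adjusted p = 0.501 and 0.501 with an estimated correlation.

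Of the immediate early and dissociation stress genes, 14 of 27 rose and 3 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.0463, adjusted p = 0.601 with an estimated correlation). This list marks handling of the tissue as well as activation, and Fos (1.32 ± 0.058) was among its members. Fos turned to -0.95 in cluster 1 alone, past the edgeR threshold. Of the cytosolic ribosomal protein genes, 7 of 32 rose and 23 fell (camera adjusted p = 0.000133, adjusted p = 0.501 with an estimated correlation). With the flow cell as a block the adjusted p was 0.052 for the cytokine list and 0.052 for the immediate early list.

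The other lists were not called, and camera adjusted p stand in parentheses. The numbers that rose, fell and did not pass were 13, 7 and 2 (0.124) for cytotoxic effector genes, in which Prf1 (1.21 ± 0.072), the pore-forming perforin, rose. They were 11, 5 and 2 (0.101) for inhibitory receptor and exhaustion genes and 7, 9 and 2 (0.785) for naive and memory progenitor genes, with Lef1 (1.89 ± 0.068) and Ly6c2 (1.75 ± 0.068) rising and Tcf7 (-0.67 ± 0.062) falling. TGF-β target genes gave 4, 10 and 2 (0.158), with Ldlrad4 (-1.19 ± 0.058), Pmepa1 (-0.85 ± 0.050) and Smad7 (-0.50 ± 0.052), each a brake on the TGF-β signal, falling. Tissue residency genes gave 6, 7 and 1 (0.505), with Itgae (-2.47 ± 0.089), which encodes the CD103 chain that binds E-cadherin, falling and Cd69 (1.17 ± 0.061) rising. Antigen processing and MHC class I genes gave 14, 5 and 1 (0.0584), and glycolysis genes 9, 3 and 4 (0.0584). Ly6c2 turned to -0.62 in cluster 5 alone and Tcf7 to 0.53 in cluster 6 alone, past the edgeR threshold. Pmepa1 turned in 1 or 2 clusters.

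In the same form, chemokine receptors gave 7, 7 and 2 (0.967). Tissue egress and circulation genes gave 5, 4 and 4 (0.724), S phase genes 3, 11 and 10 (0.207), G2 and M phase genes 5, 5 and 15 (0.859), and NF-kB and costimulation genes 7, 7 and 6 (0.932). Regulatory T cell genes gave 7, 12 and 6 (0.271), T helper 17 genes 1, 4 and 2 (0.505), T follicular helper genes 1, 4 and 4 (0.207), and mitochondrial transcripts 5, 2 and 4 (0.714). Among lists of other cell types the numbers were 0, 6 and 5 (0.271) for macrophages, 1, 4 and 1 (0.399) for dendritic cells, 1, 2 and 0 (0.309) for B cells, 2, 4 and 2 (0.724) for NK cells, 1, 2 and 0 (0.545) for endothelium, and 0, 5 and 3 (0.101) for epithelial or tumour cells. Adjusted over the list alone, the counts that rose and fell were 3 and 5 for G2 and M phase, 9 and 4 for glycolysis and 1 and 6 for macrophages, and as above for the rest. Median, mean and test differed in sign for G2 and M phase (0.017, 0.004, down), NF-kB (0.026, -0.069, down) and tissue egress (0.068, -0.004, up). Neutrophil, fibroblast and erythroid lists had too few members here.

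Of the always-named genes not yet given, Gzmb (1.16 ± 0.053), a granule protease of killer cells, Tgfbr2 (0.50 ± 0.050), the receptor whose ectodomain is in the drug, and Cd274 (0.21 ± 0.063), which encodes PD-L1, rose. Tgfb1 (-0.30 ± 0.049), Pdcd1 (-0.12 ± 0.042) and Foxp3 (-1.59 ± 0.20) fell, while Ifng stood at 0.016 ± 0.059 with an edgeR adjusted p of 0.827. Pdcd1 turned to 0.60 in cluster 5 alone, past the edgeR threshold. Cd274 turned in 3 clusters and Tgfb1 did so in 5. So the fall of Tgfb1 was seen in no cluster alone.

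**Figure D2:**
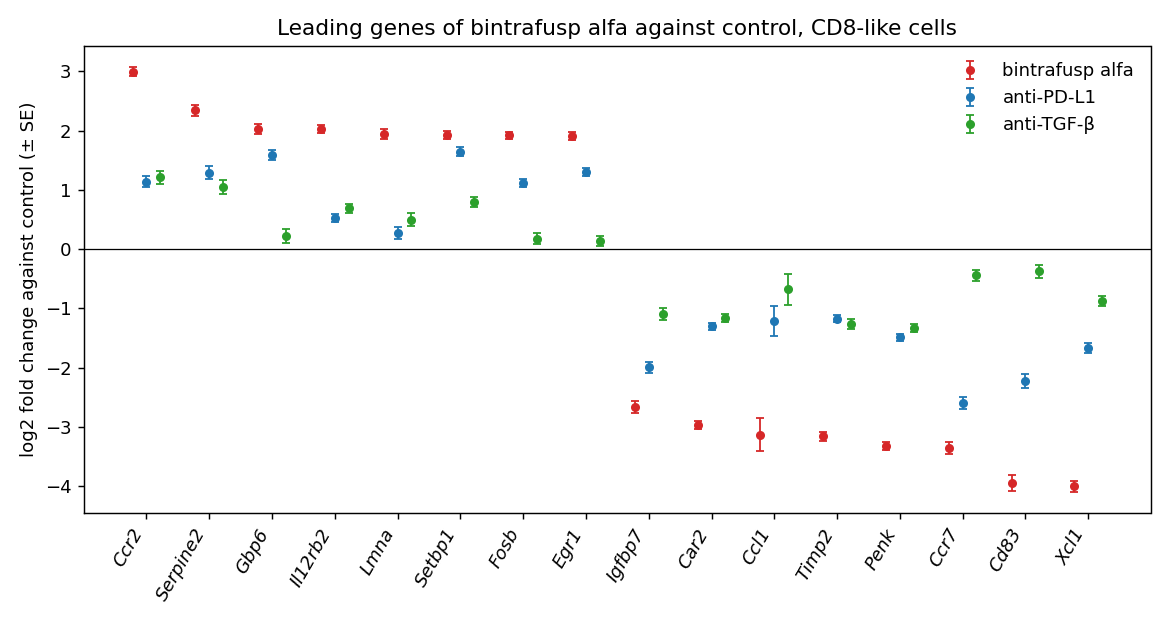
Log2 fold change against control (vertical axis, ± SE, n = 2 captures per group) in CD8-like cells for the 16 leading genes of bintrafusp alfa (horizontal axis), under each treatment. Ccr2 lies at 2.99 with bintrafusp alfa, 1.14 with anti-PD-L1 and 1.21 with anti-TGF-β, and Cd83 lies at -3.94, -2.22 and -0.37.

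Anti-PD-L1 was compared with control in CD8-like cells. Ly6a, an activation and interferon-responsive surface marker, stood at 741 ± 23.3 against 241 ± 5.94 CPM (SD, n = 2), a log2 fold change of 1.62 ± 0.047. Setbp1 (1.64 ± 0.071), Gbp6 (1.59 ± 0.086) and Prf1 (1.497 ± 0.073) also rose, as did Pik3ap1 (1.40 ± 0.083), a signalling adaptor, Il12rb1 (1.32 ± 0.092), a chain of the IL-12 receptor, and Egr1 (1.30 ± 0.069) and Serpine2 (1.29 ± 0.10). The largest fall was in Ccr7, at 72 ± 4.58 against 434 ± 5.28 CPM (SD, n = 2), a log2 fold change of -2.59 ± 0.10, followed by Krt83 (-2.29 ± 0.083), Cd83 (-2.22 ± 0.12), Igfbp7 (-1.99 ± 0.096), Tff1 (-1.82 ± 0.096), Cd74 (-1.80 ± 0.15), Bmyc (-1.78 ± 0.096) and Xcl1 (-1.67 ± 0.084). In all 2766 genes rose and 2762 fell, 5528 together, against 87 to 2302 in single clusters. Setbp1, Serpine2 and Prf1 lead cluster 3, 28.4% of these cells with anti-PD-L1 and 4.21% in control. Ccr7 and Krt83 lead cluster 6. Pik3ap1, Serpine2, Igfbp7, Cd74, Bmyc and Xcl1 turned in 1 or 2 clusters.

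Among interferon gamma response genes, 16 of 21 rose and 0 fell (camera adjusted p = 1.09e-06) and among type I interferon genes, 16 of 23 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 0.000221), with adjusted p = 0.598 and 0.598 with an estimated correlation. Of the antigen processing genes, 14 of 20 rose and 3 fell (camera adjusted p = 0.0024) and of the inhibitory receptor and exhaustion genes, 11 of 18 rose and 3 fell (camera adjusted p = 0.00181), with adjusted p = 0.598 and 0.598 with an estimated correlation. Havcr2 (0.85 ± 0.049), which encodes TIM-3, and Entpd1 (0.82 ± 0.054), which encodes CD39, were examples. Havcr2 and Entpd1 turned in 1 or 2 clusters.

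Of the glycolysis genes, 9 of 16 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0353, adjusted p = 0.682 with an estimated correlation). A block by flow cell gave an adjusted p of 0.0639. Among immediate early and dissociation stress genes, 15 of 27 rose and 4 fell (camera adjusted p = 0.0353, adjusted p = 0.682 with an estimated correlation). Gzmb (1.21 ± 0.053), Ifng (0.27 ± 0.060) and Tgfbr2 (0.26 ± 0.051) rose, while Tcf7 (-0.85 ± 0.067), Gzmd (-1.31 ± 0.17), Itgae (-0.30 ± 0.077), Smad7 (-0.21 ± 0.053), Foxp3 (-1.60 ± 0.22) and Tgfb1 (-0.15 ± 0.049) fell. Ifng turned to -0.57 in cluster 1 alone and Gzmd to 2.29 in cluster 6 alone, past the edgeR threshold. Tcf7, Smad7 and Foxp3 turned in 1 or 2 clusters, Itgae did so in 3 and Tgfb1 did so in 4. Pdcd1 stood at 0.043 ± 0.042 and Cd274 at -0.11 ± 0.068, with edgeR adjusted p of 0.444 and 0.219.

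Anti-TGF-β was compared with control in CD8-like cells. Cdk5rap1, an enzyme that modifies mitochondrial transfer RNA, stood at 41.3 ± 3.53 against 14.2 ± 0.0932 CPM (SD, n = 2), a log2 fold change of 1.54 ± 0.098. Spp1 (1.35 ± 0.17), which encodes osteopontin, Ccr2 (1.21 ± 0.11), the granzymes Gzmd (1.17 ± 0.15) and Gzme (1.12 ± 0.14), the integrin chain Itgb3 (1.054 ± 0.078) and Serpine2 (1.053 ± 0.12) and Myo10 (1.04 ± 0.11) also rose. The largest falls were in Penk (-1.33 ± 0.066), Itgae (-1.32 ± 0.10), Timp2 (-1.26 ± 0.079) and Krt83 (-1.24 ± 0.086), in Ldlrad4 (-1.17 ± 0.070), a negative regulator of TGF-β signalling, and in Car2 (-1.16 ± 0.065), Ninj1 (-1.14 ± 0.080) and Sfn (-1.12 ± 0.16), with Itgae at 20.1 ± 2.47 against 50.4 ± 0.731 CPM (SD, n = 2). Spp1, Gzmd, Gzme, Serpine2, Penk and Itgae turned in 1 or 2 clusters.

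In all 521 genes rose and 963 fell. The number was 736 without control flow cell 2, 969 without anti-TGF-β flow cell 1 and 607 without anti-TGF-β flow cell 2, against 1484. It was 894, 922, 966 and 2461 with other processing and 13 to 388 in single clusters, where other processing means the alternatives that moved a number over 1.5 times.

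Of the TGF-β target genes, 0 of 16 rose and 8 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.000126, adjusted p = 0.24 with an estimated correlation). Pmepa1 (-1.02 ± 0.058), Skil (-0.53 ± 0.061) and Smad7 (-0.42 ± 0.057), which damp the pathway that induces them, were in this list. Of the tissue residency genes, 2 of 14 rose and 8 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.000298) and of the cytotoxic effector genes, 12 of 22 rose and 4 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.0206), with adjusted p = 0.24 and 0.384 with an estimated correlation. Gzmb (0.70 ± 0.053) was among them. Of the S phase genes, 7 of 24 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000298) and of the egress and circulation genes, 7 of 13 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0335), with adjusted p = 0.652 and 0.496 with an estimated correlation. With the flow cell as a block the adjusted p was 0.0517 for egress and 0.0517 for ribosomal genes. Tgfb1 (-0.40 ± 0.051) fell, but turned in 1 or 2 clusters. Pdcd1, Tcf7, Ifng, Foxp3, Tgfbr2 and Cd274 did not pass.

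**Figure D3:**
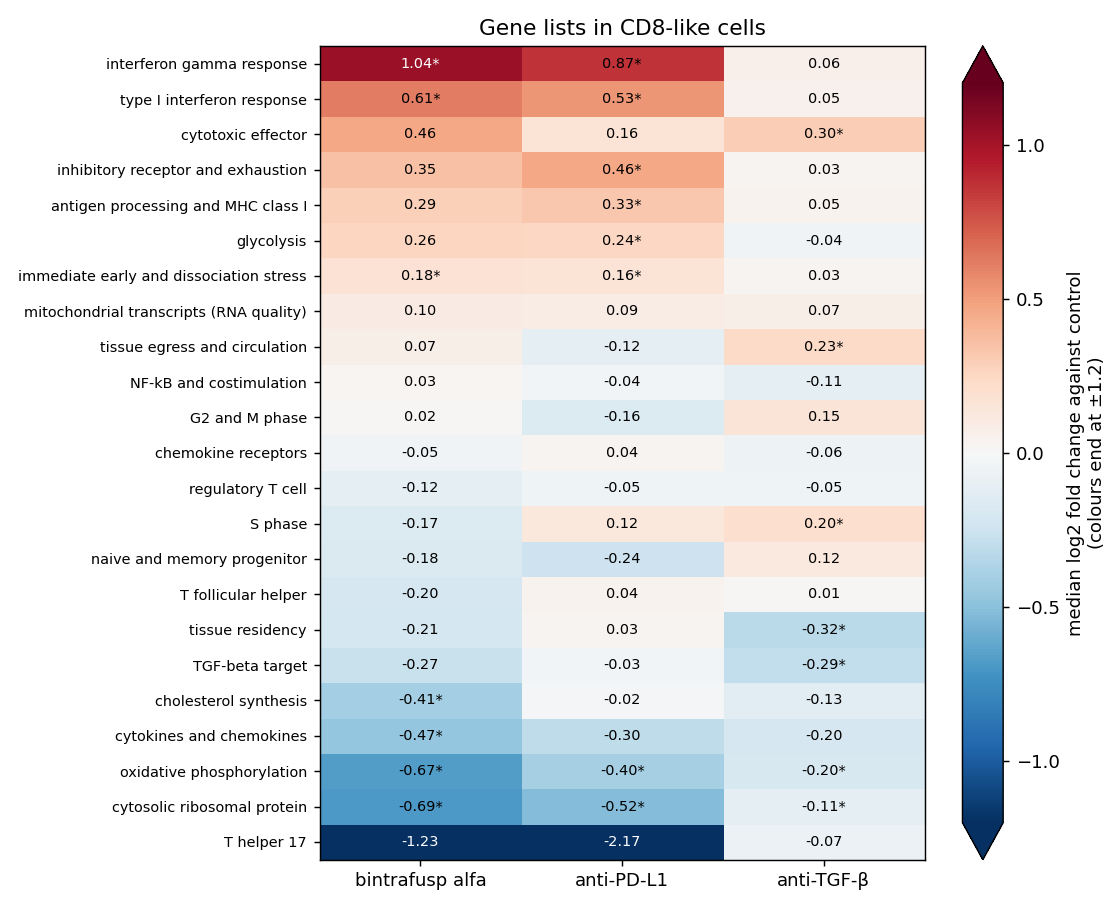
Median log2 fold change against control in CD8-like cells (colour and printed value, colours end at 1.2 either way) for 23 gene lists (vertical axis) under 3 treatments (horizontal axis); an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The interferon gamma response list has a median of 1.04 with bintrafusp alfa, 0.87 with anti-PD-L1 and 0.06 with anti-TGF-β.

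Bintrafusp alfa was also compared with anti-PD-L1 in CD8-like cells. The granzymes Gzmd (1.97 ± 0.15) and Gzme (1.94 ± 0.13) rose, as did Ccr2 (1.85 ± 0.060), Itgb3 (1.75 ± 0.059) and Lmna (1.66 ± 0.071) (SE, n = 2 per group). The largest falls were in Xcl1 (-2.33 ± 0.092), Itgae (-2.17 ± 0.086), Timp2 (-1.99 ± 0.080), C2cd4b (-1.93 ± 0.083) and Ccl1 (-1.92 ± 0.28). In all 2526 genes rose and 2403 fell, 4929 together, against 2832 and 2857 with other processing and 202 to 1384 in single clusters. Gzmd and Gzme turned in 1 or 2 clusters.

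For interferon gamma response genes, 15 of 21 rose and 2 fell (camera adjusted p = 0.00535) and among cholesterol synthesis genes, 0 of 19 rose and 16 fell (0 and 17 adjusted over the list alone, camera adjusted p = 5.46e-08), with adjusted p = 0.485 and 0.155 with an estimated correlation. Among S phase genes, 0 of 24 rose and 17 fell (0 and 18 adjusted over the list alone, camera adjusted p = 8.11e-06) and among cytokines and chemokines, 3 of 22 rose and 11 fell (camera adjusted p = 0.0239), with adjusted p = 0.476 and 0.476 with an estimated correlation. Cd274 (0.32 ± 0.059), Tgfbr2 (0.25 ± 0.047) and Tcf7 (0.18 ± 0.063) rose and Pdcd1 (-0.17 ± 0.042), Ifng (-0.25 ± 0.057), Smad7 (-0.30 ± 0.051) and Tgfb1 (-0.15 ± 0.048) fell, while Gzmb stood at -0.042 ± 0.052 and Foxp3 at 0.015 ± 0.23, neither past the threshold. Tcf7 turned to -0.22 with the gate per cell, where it fell. Cd274, Tgfbr2, Tcf7, Pdcd1, Ifng and Tgfb1 turned in 1 or 2 clusters. In no comparison were S phase genes tested in cycling-like cells, whose share was highest with bintrafusp alfa (11.1%).

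Bintrafusp alfa was then compared with anti-TGF-β. Tgtp2 (1.89 ± 0.11) and Gbp6 (1.81 ± 0.087), both interferon-induced GTPases, and Ccr2 (1.78 ± 0.073), Egr1 (1.77 ± 0.070) and Fosb (1.74 ± 0.066) rose (SE, n = 2 per group). Cd83 (-3.57 ± 0.14), Xcl1 (-3.13 ± 0.094), Ccr7 (-2.91 ± 0.10), Ccl1 (-2.45 ± 0.28) and Cd74 (-2.23 ± 0.17) fell the most. In all 3359 genes rose and 3029 fell, 6388 together, against 4038 with other processing and 474 to 1757 in single clusters. Ccr2, Ccl1 and Cd74 turned in 1 or 2 clusters.

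In interferon gamma response genes, 17 of 21 rose and 0 fell (camera adjusted p = 9.16e-07) and for type I interferon genes, 12 of 23 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.0279), with adjusted p = 0.506 and 0.613 with an estimated correlation. Among antigen processing genes, 14 of 20 rose and 3 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.0126) and among glycolysis genes, 11 of 16 rose and 2 fell (camera adjusted p = 0.00423), with adjusted p = 0.506 and 0.529 with an estimated correlation. For immediate early and dissociation stress genes, 15 of 27 rose and 0 fell (camera adjusted p = 0.00363) and for cholesterol synthesis genes, 0 of 19 rose and 11 fell (0 and 12 adjusted over the list alone, camera adjusted p = 0.000341), with adjusted p = 0.529 and 0.506 with an estimated correlation.

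For S phase genes, 1 of 24 rose and 14 fell (1 and 15 adjusted over the list alone, camera adjusted p = 0.000277) and for cytokines and chemokines, 3 of 22 rose and 14 fell (camera adjusted p = 0.0109), with adjusted p = 0.592 and 0.506 with an estimated correlation. Tgfbr2 (0.59 ± 0.052), Gzmb (0.47 ± 0.053) and Cd274 (0.28 ± 0.070) rose and Itgae (-1.15 ± 0.12), Tcf7 (-0.79 ± 0.066), Foxp3 (-1.89 ± 0.21) and Pdcd1 (-0.16 ± 0.042) fell. Gzmb, Cd274, Itgae, Tcf7 and Pdcd1 turned in 1 or 2 clusters.

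Additivity compared bintrafusp alfa with the summed log-scale changes of the single antibodies. The departure was above the sum for Lmna (1.16 ± 0.14), Krt83 (1.09 ± 0.13), Rgcc (1.07 ± 0.10), Ly6c2 (1.052 ± 0.095) and Lef1 (0.99 ± 0.11) (SE, n = 2 per group). It was below the sum for Cdk5rap1 (-2.28 ± 0.12), Ccl3 (-1.99 ± 0.15), C2cd4b (-1.62 ± 0.12), Spp1 (-1.58 ± 0.23) and Xcl1 (-1.46 ± 0.12). In all 699 genes lay above and 541 below, 1240 together, against 452 and 665 with other processing and 14 to 83 in single clusters, where most lay below in 4 of 5. Rgcc, C2cd4b and Spp1 turned in 1 or 2 clusters and Ly6c2 did so in 3.

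In S phase genes, 0 of 24 lay above the sum and 15 below (0 and 22 adjusted over the list alone, camera adjusted p = 7.88e-12) and in cholesterol synthesis genes, 0 of 19 lay above the sum and 4 below (0 and 8 adjusted over the list alone, camera adjusted p = 1.89e-06), with adjusted p = 0.493 and 0.23 with an estimated correlation. Among inhibitory receptor and exhaustion genes, 2 of 18 lay above the sum and 9 below (camera adjusted p = 0.00603) and among TGF-β target genes, 7 of 16 lay above the sum and 1 below (8 and 1 adjusted over the list alone, camera adjusted p = 0.0406), with adjusted p = 0.607 and 0.493 with an estimated correlation. For this list a block by flow cell gave an adjusted p of 0.0579. In cytokines and chemokines, 2 of 22 lay above the sum and 10 below (4 and 12 adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.556 with an estimated correlation).

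In conventional CD4-like cells bintrafusp alfa was compared with control. Gzmc (2.54 ± 0.43), a granzyme, Serpinb1a (1.79 ± 0.18), a protease inhibitor, Filip1l (1.76 ± 0.10), Egr1 (1.75 ± 0.15) and Il12rb2 (1.68 ± 0.11) rose (SE, n = 2 per group). Il17a (-6.28 ± 0.95), the cytokine of T helper 17 cells, fell the most, followed by Xcl1 (-3.62 ± 0.58), Def8 (-2.19 ± 0.27), Il2 (-2.16 ± 0.41) and Krt83 (-2.09 ± 0.12). In all 1844 of 10462 genes rose and 1857 fell, 3701 together, against 2097 with other processing. Clusters 7 and 8 were 67.4% and 32.6% of this class with bintrafusp alfa and 55.4% and 44.6% in control, and Cd8a stood at 103 ± 27.1 CPM against 47.9 ± 5.44 (SD, n = 2).

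Within the interferon gamma response genes, 13 of 19 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 0.00113) and for inhibitory receptor and exhaustion genes, 10 of 18 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.00241), with adjusted p = 0.531 and 0.531 with an estimated correlation. For TGF-β target genes, 2 of 15 rose and 9 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.531 with an estimated correlation). Of the T helper 17 genes, 2 of 13 rose and 5 fell (camera adjusted p = 0.0313) and of the G2 and M phase genes, 7 of 19 rose and 0 fell (camera adjusted p = 0.0206), with adjusted p = 0.531 and 0.758 with an estimated correlation. Within the cholesterol synthesis genes, 0 of 19 rose and 5 fell (camera adjusted p = 0.0175, adjusted p = 0.731 with an estimated correlation). Ifng (0.52 ± 0.12) and Tgfbr2 (0.37 ± 0.097) rose and Tgfb1 (-0.27 ± 0.083) fell. Ifng stood at -0.01 in thinned cells.

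With anti-PD-L1, conventional CD4-like cells carried more of the chemokines Ccl3 (2.83 ± 0.30) and Ccl4 (2.72 ± 0.31), more perforin as Prf1 (2.17 ± 0.25), and more Csf1 (2.11 ± 0.12) and Gzmd (1.67 ± 0.55) (SE, n = 2 per group). Il2 (-3.53 ± 0.44), the T cell growth factor, fell the most, with Krt83 (-1.79 ± 0.11), Trat1 (-1.60 ± 0.19), Rflnb (-1.57 ± 0.22) and Shld1 (-1.38 ± 0.13). In all 922 genes rose and 1154 fell, 2076 together, against 1027 and 1318 with other processing. The number was 1249 without control flow cell 1, 988 without control flow cell 2 and 1015 without anti-PD-L1 flow cell 2. Cluster 7 was 73.4% of the class, against 55.4% in control.

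In inhibitory receptor and exhaustion genes, 15 of 18 rose and 0 fell (camera adjusted p = 1.41e-08, adjusted p = 0.0842 with an estimated correlation). Pdcd1 (0.31 ± 0.068) was among them. Among cytotoxic effector genes, 12 of 21 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00055) and of the naive and memory progenitor genes, 1 of 18 rose and 11 fell (camera adjusted p = 0.000388), with adjusted p = 0.216 and 0.216 with an estimated correlation. Among egress and circulation genes, 1 of 12 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.00584) and of the interferon gamma response genes, 8 of 19 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0033), with adjusted p = 0.255 and 0.386 with an estimated correlation. For antigen processing genes, 12 of 20 rose and 3 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.0188, adjusted p = 0.498 with an estimated correlation). Gzmb (1.46 ± 0.34) rose, and turned to -0.30 with the gate per cell, where it did not pass.

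For glycolysis genes, 8 of 16 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0396, adjusted p = 0.7 with an estimated correlation). For glycolysis a block by flow cell gave an adjusted p of 0.066. Of the regulatory T cell genes, 9 of 25 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.0328, adjusted p = 0.255 with an estimated correlation). Foxp3 stood at 0.11 ± 0.54 and did not pass. Ifng (1.02 ± 0.12) rose.

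With anti-TGF-β, conventional CD4-like cells carried more Il5 (2.14 ± 0.40), a type 2 cytokine, Hspa1b (1.78 ± 0.24), a heat shock protein, Cdk5rap1 (1.55 ± 0.16), Gzmb (1.47 ± 0.35) and Ero1l (1.30 ± 0.24) (SE, n = 2 per group). Gzma (-2.15 ± 0.38), Gpr25 (-2.09 ± 0.27), Il2 (-1.961 ± 0.41), Slc15a2 (-1.30 ± 0.24) and Tff1 (-1.24 ± 0.14) fell. Il5 varied between captures, at 298 ± 253 against 68.4 ± 15.3 CPM (SD, n = 2). In all 109 genes rose and 154 fell, 263 together, against 426 and 498 with other processing. The number was 80 and 87 without control flow cell 1 or 2, 94 without anti-TGF-β flow cell 1 (53 rose and 41 fell) and 71 without anti-TGF-β flow cell 2.

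In TGF-β target genes, 0 of 15 rose and 7 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.000235, adjusted p = 0.362 with an estimated correlation). Among naive and memory progenitor genes, 3 of 18 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.362 with an estimated correlation). Ifng (-0.91 ± 0.13) and Tgfb1 (-0.43 ± 0.084) fell.

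In regulatory T-like cells bintrafusp alfa was compared with control. Klf3 (2.46 ± 0.27), a factor of quiescent lymphocytes, Cxcl10 (2.37 ± 0.14), an interferon-induced chemokine, Cdc25b (2.01 ± 0.17), a cell cycle phosphatase, Emb (1.90 ± 0.11) and Insyn2b (1.90 ± 0.22) rose (SE, n = 2 per group). Tff1 (-4.12 ± 0.31), a trefoil peptide of epithelia, Def8 (-3.34 ± 0.32), the interferon-induced Ifitm3 (-3.03 ± 0.28), Apol9b (-2.72 ± 0.26) and Alg9 (-2.69 ± 0.26), an enzyme of glycan assembly, fell the most. Tcf7 (2.05 ± 0.32), Foxp3 (0.34 ± 0.071), Tgfbr2 (0.57 ± 0.15) and Cd274 (0.33 ± 0.092) rose and Gzmb (-0.87 ± 0.060), Itgae (-1.42 ± 0.096), Ifng (-1.68 ± 0.42), Pdcd1 (-0.63 ± 0.082), Tgfb1 (-0.47 ± 0.10) and Smad7 (-0.31 ± 0.096) fell. In all 1464 of 11152 genes rose and 1845 fell, 3309 together, against 2051 with other processing. The bintrafusp alfa captures held 244 such cells, the control captures 2785.

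Among interferon gamma response genes, 13 of 20 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.000201) and in type I interferon genes, 12 of 24 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00163), with adjusted p = 0.305 and 0.45 with an estimated correlation. For egress and circulation genes, 8 of 12 rose and 2 fell (camera adjusted p = 0.00751) and for naive and memory progenitor genes, 8 of 17 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00751), with adjusted p = 0.305 and 0.305 with an estimated correlation. Within the TGF-β target genes, 2 of 16 rose and 7 fell (camera adjusted p = 0.038) and among regulatory T cell genes, 4 of 26 rose and 13 fell (camera adjusted p = 0.0329), with adjusted p = 0.45 and 0.305 with an estimated correlation.

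In immediate early and dissociation stress genes, 9 of 27 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.57 with an estimated correlation).

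With anti-PD-L1, regulatory T-like cells carried more Kcna3 (1.48 ± 0.16), a potassium channel of T cells, Prf1 (1.47 ± 0.18), Egr1 (1.40 ± 0.18), Cxcl10 (1.40 ± 0.12) and Filip1l (1.27 ± 0.088) (SE, n = 2 per group). Ccr7 (-1.02 ± 0.20), Csrp2 (-0.998 ± 0.12), Ramp3 (-0.93 ± 0.17), Rapsn (-0.87 ± 0.099) and Slc25a4 (-0.85 ± 0.090) fell. Foxp3 (0.46 ± 0.065), Itgae (0.51 ± 0.063) and Cd274 (0.40 ± 0.069) rose and Ifng (-1.01 ± 0.23) fell. In all 1054 genes rose and 1545 fell, 2599 together, against 1398 with other processing. The number was 1480 without control flow cell 2 and 1550 without anti-PD-L1 flow cell 2. Ifng turned to 0.30 with the gate per cell, where it did not pass.

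For interferon gamma response genes, 19 of 20 rose and 0 fell (camera adjusted p = 6.78e-12) and within the type I interferon genes, 9 of 24 rose and 1 fell (camera adjusted p = 0.000378), with adjusted p = 0.131 and 0.625 with an estimated correlation. In antigen processing genes, 11 of 20 rose and 4 fell (13 and 5 adjusted over the list alone, camera adjusted p = 0.00699) and within the inhibitory receptor and exhaustion genes, 11 of 18 rose and 0 fell (camera adjusted p = 0.00939), with adjusted p = 0.625 and 0.276 with an estimated correlation. Of the NF-kB and costimulation genes, 9 of 20 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0245) and within the immediate early and dissociation stress genes, 11 of 27 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0172), with adjusted p = 0.625 and 0.709 with an estimated correlation.

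With anti-TGF-β, regulatory T-like cells carried more Cdk5rap1 (1.69 ± 0.12), Csf1 (1.19 ± 0.12), Nrn1 (1.09 ± 0.15), Serpinb6b (1.06 ± 0.11) and Gpr55 (1.02 ± 0.088) (SE, n = 2 per group). Ctsw (-2.10 ± 0.078), a cathepsin of cytotoxic lymphocytes, fell the most, at 62.3 ± 6.42 against 266 ± 3.66 CPM (SD, n = 2), followed by Apol9b (-1.73 ± 0.12), Rgs16 (-1.65 ± 0.084), Tff1 (-1.60 ± 0.13) and Plac8 (-1.36 ± 0.22). In all 218 genes rose and 577 fell, 795 together, against 139, 335 and 475 with other processing. The number was 251 without control flow cell 2, and 256 and 213 without anti-TGF-β flow cell 1 or 2. Gzmb (0.34 ± 0.057) rose and Itgae (-0.67 ± 0.065), Tgfb1 (-0.51 ± 0.082) and Smad7 (-0.36 ± 0.072) fell.

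Of the TGF-β target genes, 0 of 16 rose and 9 fell (camera adjusted p = 7.26e-08) and among tissue residency genes, 0 of 13 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.0154), with adjusted p = 0.23 and 0.241 with an estimated correlation. For cytotoxic effector genes, 7 of 19 rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0338) and in glycolysis genes, 5 of 16 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 4.01e-05), with adjusted p = 0.241 and 0.302 with an estimated correlation. For regulatory T cell genes, 1 of 26 rose and 7 fell (4 and 11 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.241 with an estimated correlation).

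In naive and memory progenitor genes, 4 of 17 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.022) and among G2 and M phase genes, 1 of 17 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0158), with adjusted p = 0.241 and 0.25 with an estimated correlation.

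Lists called often are given together. In CD8-like clusters 1, 2, 3, 5 and 6 alone, 22, 0, 17, 20 and 19 of 32 oxidative phosphorylation genes fell with anti-PD-L1. With anti-TGF-β 0, 0, 0, 7 and 0 fell. At most 1 rose in each. Oxidative phosphorylation genes, which encode the respiratory chain, rose and fell in CD8-like cells as 1 and 30 of 32 with anti-PD-L1 (camera adjusted p = 2.72e-09) and 0 and 22 of 32 with anti-TGF-β (0 and 25 adjusted over the list alone, camera adjusted p = 4.18e-07), with adjusted p = 0.598 and 0.652 with an estimated correlation. The numbers were 0 and 29 of 32 for bintrafusp alfa against anti-PD-L1 (camera adjusted p = 8.6e-10) and 0 and 29 of 32 for bintrafusp alfa against anti-TGF-β (camera adjusted p = 3.31e-10), with adjusted p = 0.476 and 0.529 with an estimated correlation, and 0 and 3 of 32 above and below the sum (0 and 5 adjusted over the list alone, camera adjusted p = 0.0277), with adjusted p = 0.789 with an estimated correlation. In conventional CD4-like cells they were 0 and 29 of 32 with bintrafusp alfa (camera adjusted p = 2.7e-13), 1 and 25 of 32 with anti-PD-L1 (camera adjusted p = 3.6e-10) and 0 and 5 of 32 with anti-TGF-β (0 and 10 adjusted over the list alone, camera adjusted p = 4.69e-07), with adjusted p = 0.531, 0.452 and 0.987 with an estimated correlation. In regulatory T-like cells they were 1 and 29 of 32 with bintrafusp alfa (1 and 30 adjusted over the list alone, camera adjusted p = 1.1e-10), 0 and 29 of 32 with anti-PD-L1 (1 and 30 adjusted over the list alone, camera adjusted p = 2.65e-15) and 0 and 17 of 32 with anti-TGF-β (0 and 23 adjusted over the list alone, camera adjusted p = 2.21e-09), with adjusted p = 0.391, 0.378 and 0.302 with an estimated correlation.

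Cytosolic ribosomal protein genes rose and fell in CD8-like cells as 8 and 23 of 32 with anti-PD-L1 (camera adjusted p = 0.000175), 2 and 14 of 32 with anti-TGF-β (2 and 17 adjusted over the list alone, camera adjusted p = 0.0336), 0 and 20 of 32 for bintrafusp alfa against anti-PD-L1 (1 and 22 adjusted over the list alone, camera adjusted p = 0.000349) and 6 and 23 of 32 for bintrafusp alfa against anti-TGF-β (camera adjusted p = 1.68e-05), with adjusted p = 0.598, 0.747, 0.476 and 0.506 with an estimated correlation. In conventional CD4-like cells they did so as 9 and 21 of 32 with bintrafusp alfa (camera adjusted p = 0.00113) and 6 and 22 of 32 with anti-PD-L1 (8 and 23 adjusted over the list alone, camera adjusted p = 3.59e-07), with adjusted p = 0.731 and 0.386 with an estimated correlation, and in regulatory T-like cells as 6 and 21 of 32 with anti-PD-L1 (8 and 23 adjusted over the list alone, camera adjusted p = 1.58e-07), with adjusted p = 0.252 with an estimated correlation. Epithelial and tumour cell markers, a sign of foreign RNA, did so in CD8-like cells as 0 and 2 of 8 with anti-TGF-β (0 and 3 adjusted over the list alone, camera adjusted p = 0.0336) and 0 and 5 of 8 for bintrafusp alfa against anti-PD-L1 (camera adjusted p = 0.0337), with adjusted p = 0.384 and 0.476 with an estimated correlation, and in regulatory T-like cells as 0 and 3 of 7 with bintrafusp alfa (0 and 4 adjusted over the list alone, camera adjusted p = 0.0329) and 0 and 3 of 7 with anti-TGF-β (0 and 4 adjusted over the list alone, camera adjusted p = 0.000681), with adjusted p = 0.305 and 0.23 with an estimated correlation. In regulatory T-like cells neutrophil markers gave 1 and 0 of 3 with anti-TGF-β (2 and 0 adjusted over the list alone, camera adjusted p = 0.0343), with adjusted p = 0.25 with an estimated correlation, and mitochondrial transcripts, a sign of RNA quality, 6 and 1 of 11 with bintrafusp alfa (8 and 1 adjusted over the list alone, camera adjusted p = 0.0329), with adjusted p = 0.553 with an estimated correlation.

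Over all retained cells, where class shares and expression are mixed, 4782 of 14943 genes rose and 4667 fell with bintrafusp alfa, 3543 rose and 3169 fell with anti-PD-L1, and 1668 rose and 2247 fell with anti-TGF-β. The last pair, 3915 together, came to 2419 without control flow cell 2 and 2000 without anti-TGF-β flow cell 2.

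The class by treatment term compared CD8-like with regulatory T-like cells. With bintrafusp alfa Gzmb rose in CD8-like cells and fell in regulatory T-like cells, a difference of 2.03 ± 0.058 in log2 fold change (SE, n = 2 per group and class), while Tcf7, a factor of stem-like T cells, differed by -2.72 ± 0.31. With anti-PD-L1 the integrin gene Itgae differed by -0.84 ± 0.083, and with anti-TGF-β Plac8 differed by 1.60 ± 0.21. Of 12365 genes tested by edgeR, the CD8-like minus regulatory T-like log2 fold change with bintrafusp alfa was above 0 for 929 and below 0 for 681, 1610 together, against 744 and 822 with other processing. The numbers were 242 and 268 with anti-PD-L1 (510 together, against 222 with other processing) and 162 and 167 with anti-TGF-β (329 together, against 52 and 204 with other processing). For anti-PD-L1 the number was 288 and 244 without control flow cell 1 or 2, and for anti-TGF-β 187 and 130 without these and 165 and 160 without anti-TGF-β flow cell 1 or 2.

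Clonotype tables pool all T cell classes and rank as CD8-like shares do, so clone expansion was not separated from class shares. The 10 largest clonotypes held 30.7% (95% interval 29.3 to 32.2) and 30.05% (28.6 to 31.5) of cells in the bintrafusp alfa tables, 17.4% (16.3 to 18.5) and 18.4% (17.3 to 19.6) in those of anti-PD-L1, 14.8% (13.9 to 15.7) in control flow cell 2 and 11.8% (10.7 to 12.9) in anti-TGF-β flow cell 1. Thinned to the 3554 cells of the smallest table, the 10 largest held 18.5% in anti-PD-L1 flow cell 2 and as above elsewhere. Clonotypes of 2 or more cells then held 78.8% and 79.0% of cells with bintrafusp alfa, 65.0% and 68.1% with anti-PD-L1, 59.3% in control and 52.2% with anti-TGF-β, and clonality was 0.198 and 0.198, 0.113 and 0.119, 0.095 and 0.075 in that order. Control and anti-TGF-β have 1 table each, so neither was tested. Bintrafusp alfa against anti-PD-L1 cannot go below an exact permutation p of 0.333.

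**Figure D4:**
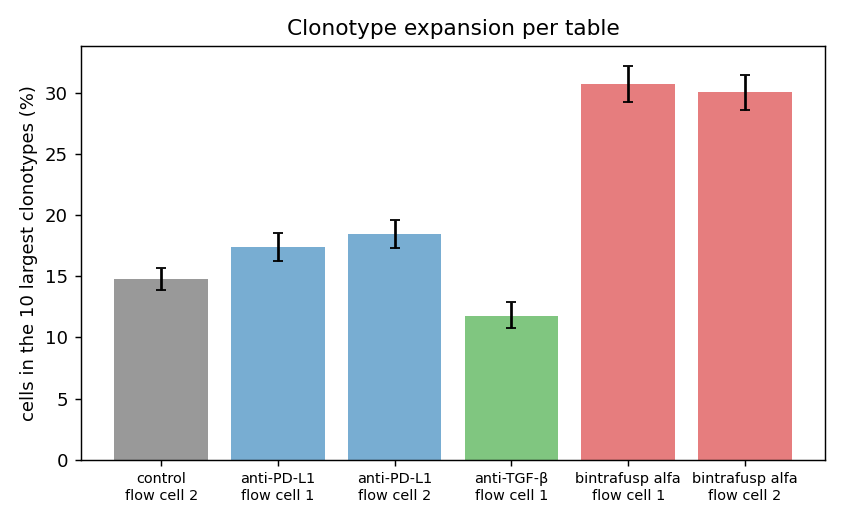
Share of cells in the 10 largest clonotypes (%, vertical axis) of each of 6 clonotype tables (horizontal axis), with exact binomial 95% intervals. The bintrafusp alfa tables reach 30.7% and 30.05%, and the others lie between 11.8% and 18.4%.

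Captures of a treatment shared most large clones. The Morisita-Horn index was 0.951 ± 0.0067 between the anti-PD-L1 tables, with 487 shared clonotypes, and 0.962 ± 0.0059 between the bintrafusp alfa tables, with 273 (SD over redraws). Between different treatments it did not exceed 0.0222 over 13 pairs, with 0 to 30 shared clonotypes. Those shared by anti-PD-L1 and bintrafusp alfa held 24.5% to 30.1% of cells in the bintrafusp alfa tables and 2.83% to 4.2% in the anti-PD-L1 tables, against at most 2.93% of either table in pairs of other treatments. By TRB amino acid sequence alone the highest index between treatments was 0.0956, with at most 90 shared.

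V segment usage in CD8-like cells was read from the RNA. Trbv13-1 gave 28.4% ± 1.36 of Trbv UMIs with bintrafusp alfa (SD, n = 2), 9.37% ± 0.09 in control, 8.88% ± 0.06 with anti-PD-L1 and 14.6% ± 0.31 with anti-TGF-β. Trbv1 gave 14.8% ± 0.18 with anti-PD-L1 and 2.21% ± 0.09 in control. For both segments the exact permutation p was 0.0095, with an adjusted p of 0.0258. The effective number of segments was 12.5 ± 0.38 with bintrafusp alfa, 15.3 ± 0.22 in control, 15.8 ± 0.25 with anti-PD-L1 and 15.99 ± 0.28 with anti-TGF-β, with an exact permutation p of 0.019 (within flow cells 0.0833). Counted by cells it was 12.8, 16.9, 15.6 and 14.9, so the differences of anti-PD-L1 and anti-TGF-β from control turned.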

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

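Of the named genes whose response differed between CD8-like and regulatory T-like cells (102 of 160 with bintrafusp alfa, 60 of 148 with anti-PD-L1 and 48 of 137 with anti-TGF-β), 27 results had opposite changes that both passed the edgeR test, and those reported are given here as the CD8-like minus the regulatory T-like log2 fold change, followed by the value in each class. With bintrafusp alfa Gzmb 2.03 (1.16 and -0.87), Entpd1 1.955 (0.66 and -1.30) and Icos 1.01 (0.44 and -0.58) had higher values in CD8-like cells. So had the homing receptors Ccr1 2.72 (1.42 and -1.30) and Cxcr6 2.19 (0.22 and -1.97), and Alg9 3.12 (0.44 and -2.69), an enzyme of glycan assembly. Lower there were Tcf7 -2.72 (-0.67 and 2.05) and Slamf6 -1.61 (-0.78 and 0.83), both of stem-like T cells, and Foxp3 -1.93 (-1.59 and 0.34), Itgb1 -1.87 (-0.42 and 1.45) and Ccr4 -2.16 (-0.99 and 1.17).

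With anti-PD-L1 the values of Ifng 1.245 (0.27 and -1.01), Gzma 2.32 (0.47 and -1.89) and Ccl5 1.498 (0.85 and -0.68), products of killer cells, Itga4 0.83 (0.38 and -0.49), an integrin chain, and Igkc 1.196 (0.50 and -0.73), an immunoglobulin chain that T cells do not make, were higher in CD8-like cells. Those of Foxp3 -2.09 (-1.60 and 0.46) and Lrrc32 -2.45 (-1.87 and 0.56), both of regulatory T cells, Itgae -0.84 (-0.30 and 0.51), Cd74 -2.18 (-1.80 and 0.34), Gpr183 -0.90 (-0.57 and 0.29), Rora -0.63 (-0.37 and 0.22) and Nr4a3 -0.74 (-0.20 and 0.50) were lower. With anti-TGF-β Plac8 1.60 (0.26 and -1.36) and Entpd1 0.49 (0.20 and -0.31) were higher and Slc16a3 -0.61 (-0.34 and 0.25) lower. Class values of Tcf7, Slamf6, Ifng, Igkc, Rora, Nr4a3 and Cd74 turned, past the edgeR threshold, in a single cluster or with the gate per cell. Without passing, CD8-like values had the other sign in 3 of 5 clusters alone for Itgae with anti-PD-L1 and Entpd1 with anti-TGF-β, in 2 for Plac8 with anti-TGF-β, in 1 or 2 for Itga4, Gpr183 and Ccl5 with anti-PD-L1 and Entpd1, Cxcr6, Icos and Alg9 with bintrafusp alfa, and in 1 of 4 for Foxp3 with anti-PD-L1. Gzma with anti-PD-L1 turned in regulatory T-like cells (0.072) without the top doublet scores. Foxp3 stood at 2.51 CPM in CD8-like cells with bintrafusp alfa and 6.49 in control, so its change there rests on few transcripts. Cd8a stood at 37.1 CPM in regulatory T-like cells with bintrafusp alfa and 25.2 in control.

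Tests of the regulatory T-like share and of shared clonotypes were chosen after seeing the results, and those of oxidative phosphorylation before. Regulatory T-like cells were 2.64% of cells with bintrafusp alfa and 22.2% in control. The gate per cell gave a smaller fall, 95 of 4478 and 86 of 4784 cells against 440 of 5311 and 459 of 7195. With cells thinned to 3000 UMIs, 3.99% carried a Foxp3 UMI against 17.9%, a ratio of 0.2229 where a depth gap alone needed 0.8 or more. This left out 389 and 3154 shallower cells. Unthinned, with none left out, the captures gave 5.96% and 4.98% against 24.0% and 22.7%, although bintrafusp alfa cells were deeper. The 5.96% and 4.98% exceed the class share of 2.64%. Over all retained cells Foxp3 stood at 29.7 against 113 CPM, a ratio of 0.2632. So such cells placed in other clusters may give part of the fall but not all. As a percentage of regulatory T-like plus conventional CD4-like cells they were 28.4% against 62.5%, a difference of -34.06 points, which dilution by CD8-like cells alone would not give. Loss of these cells in the 1 pool of mice remains open, as do differences in dissociation or sorting, which were not tested.

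Oxidative phosphorylation genes had a median log2 fold change of -0.667 with bintrafusp alfa in CD8-like cells. In cells of 5000 to 8000 UMIs from every capture it was -0.878, where a depth gap needed a value within 0.1 of 0. In clusters 1, 2, 3, 5 and 6 alone it was -0.364, -0.211, -0.449, -0.573 and -0.521, at or below -0.3 in 4 of 5. All are weaker than -0.667, so different clusters in the groups may give part of the fall but not all. Cluster 2, the largest with bintrafusp alfa, held 38 control cells. A difference between the pools in handling time remains open.

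Of 60 bintrafusp alfa clonotypes of 20 or more cells, 23 were seen in the anti-PD-L1 tables, as 48 cells or 1.10 per 100, where 1 rate for every clonotype gave 25.6 (range 19 to 32), so carry-over of cells or reads into the anti-PD-L1 libraries may be the source. Of 53 anti-PD-L1 clonotypes of that size 3 were seen in the bintrafusp alfa tables, below the 8.46 (range 4 to 14) of carry-over the other way, and 0 of the 60 bintrafusp alfa clonotypes were seen in the control and anti-TGF-β tables, which argues against receptors that arise alike in any mouse for clonotypes of that size. Of any size, 3 were shared between control and each bintrafusp alfa table, so the smaller shared clonotypes stay open. These tests replaced earlier ones after their outcomes had been seen. In the first form, carry-over either way needed 80% or more of clonotypes of 50 or more cells to be seen in the other treatment and was argued against below 50%: 14 of 38 (36.8%) were seen, which counted against carry-over either way. Taken apart, 12 of 24 (50%) bintrafusp alfa clonotypes were seen with anti-PD-L1, not below that bound, and 2 of 14 (14.3%) the other way. The form was replaced because 1 rate leaves many unseen (20.6 of 38 expected). The first form for like receptors, 30 shared clonotypes against at most 13 in other pairs, a ratio of 2.31 around a bound of 3, decided nothing, and the minimum of 20 cells was also chosen afterwards.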

How the results depend on the processing

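The treatments were each 1 pool of mice, so no alternative separates treatment from pool. Named genes gave 8735 alternative values for 448 results, of which 139 had the other sign, 130 of them in single CD8-like clusters. The named results followed in this way were narrowed from all named genes to these 448 after reversals had been seen, and single clusters were kept. Where a capture is left out, its lone partner is assumed to vary like the captures of the other groups. The cause of the differences below was not tested.

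Numbers in parentheses are from edgeR as reported. By the DESeq2 Wald test the number of genes changed in CD8-like cells was 894 (1484) for anti-TGF-β against control, 2857 (4929) for bintrafusp alfa against anti-PD-L1 and 665 (1240) for additivity. It was 2097 (3701) and 1027 (2076) for bintrafusp alfa and anti-PD-L1 in conventional CD4-like cells, and 1398 (2599) and 335 (795) for anti-PD-L1 and anti-TGF-β in regulatory T-like cells. With no filter anti-TGF-β gave 966 (1484) in CD8-like and 498 (263) in conventional CD4-like cells. With the gate per cell anti-TGF-β gave 2461 (1484), 426 (263) and 139 (795) in CD8-like, conventional CD4-like and regulatory T-like cells, and the class by treatment term 822 (1610), 222 (510) and 52 (329) for bintrafusp alfa, anti-PD-L1 and anti-TGF-β. Thinning left 922 (1484) for anti-TGF-β, 2832 (4929) and 4038 (6388) for bintrafusp alfa against anti-PD-L1 and anti-TGF-β, and 452 (1240) for additivity in CD8-like cells, 1318 (2076) for anti-PD-L1 in conventional CD4-like cells, 2051 (3309) and 475 (795) for bintrafusp alfa and anti-TGF-β in regulatory T-like cells, and 744 (1610) and 204 (329) for the class by treatment term of the same treatments.

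Splits into higher and lower genes shifted by the DESeq2 Wald test to 797 and 1300 (1844 and 1857), 338 and 689 (922 and 1154) and 51 and 135 (109 and 154) for bintrafusp alfa, anti-PD-L1 and anti-TGF-β in conventional CD4-like cells and to 414 and 984 (1054 and 1545) for anti-PD-L1 in regulatory T-like cells. For the class by treatment term with anti-PD-L1 the split was 428 and 301 (242 and 268) with no filter, 64 and 158 (242 and 268) with the gate per cell and 277 and 159 (242 and 268) in thinned cells, and with anti-TGF-β 33 and 19 (162 and 167) with the gate.

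In clusters 1, 2, 3, 5 and 6 alone the numbers were 2202, 173, 1715, 3299 and 2001 for bintrafusp alfa, 2302, 87, 747, 1377 and 1411 for anti-PD-L1, 223, 13, 110, 388 and 201 for anti-TGF-β, 203, 1281, 1287, 1384 and 202 for bintrafusp alfa against anti-PD-L1, 1345, 474, 1757, 1643 and 850 against anti-TGF-β and 83, 14, 47, 40 and 34 for additivity. Higher and lower genes were split differently from the whole class in cluster 2 for anti-TGF-β (7 and 6), bintrafusp alfa against anti-TGF-β (164 and 310) and additivity (2 and 12), in cluster 3 for anti-PD-L1 (260 and 487) and additivity (21 and 26), in cluster 5 for additivity (9 and 31), and in cluster 6 for anti-TGF-β (91 and 110) and additivity (13 and 21).

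Leaving out each capture in turn gave ranges of 607–1596 genes for anti-TGF-β in CD8-like cells, 988–2190 and 71–311 for anti-PD-L1 and anti-TGF-β in conventional CD4-like cells, 1480–2888 and 213–948 in regulatory T-like cells, 2000–4135 for anti-TGF-β in all retained cells, and 244–717 and 130–462 for the class by treatment term. For shares against control the ranges in percentage points were -0.16 to 0.50 for cycling-like and -0.24 to 0.24 for interferon-high-like cells with anti-TGF-β, and -0.11 to 0.13 for unnamed cells with anti-PD-L1.

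Differences in share from control turned at resolution 0.5 for conventional CD4-like cells with anti-PD-L1 (1.52), cycling-like (-0.29) and interferon-high-like cells (-0.090) with anti-TGF-β, and unnamed cells with anti-PD-L1 (-2.03). At resolution 2.0 interferon-high-like cells with anti-TGF-β stood at -0.070. The gate per cell gave 1.85 and 1.97 for conventional CD4-like and regulatory T-like cells with anti-PD-L1. Without the top doublet scores cycling-like cells with anti-TGF-β stood at -0.050 and unnamed cells with bintrafusp alfa at 0.28, and with doublets kept unnamed cells with anti-PD-L1 stood at -1.03.

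Outside single clusters 9 values of named genes turned. In CD8-like cells Nr4a3 with anti-PD-L1 stood at 0.080 with doublets kept and 0.17 with the gate per cell, which also gave Tcf7 -0.22 for bintrafusp alfa against anti-PD-L1 and Mcm5 0.16 for additivity. In conventional CD4-like cells Gzmb with anti-PD-L1 stood at -0.30 with the gate and Ifng with bintrafusp alfa at -0.011 in thinned cells. In regulatory T-like cells with anti-PD-L1, Ifng stood at 0.30 and Cd74 at -0.87 with the gate, and Gzma at 0.072 without the top doublet scores.

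In cluster 1 alone these genes turned with bintrafusp alfa: Cd274 -0.063, Tgfb1 0.023, Pmepa1 0.056 and Fos -0.95. Cluster 1 with anti-PD-L1 gave Itgae 0.15 and Ifng -0.57. Cluster 1 with anti-TGF-β gave Penk 0.71. Against anti-PD-L1 cluster 1 gave Tgfb1 0.17, Hells 0.26 and Fdps 0.14. Against anti-TGF-β cluster 1 gave Cd274 -0.015, Itgae 0.13 and Tnfsf11 0.45. Additivity in cluster 1 gave Ly6c2 -0.052 and C2cd4b 0.048.

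In cluster 2 alone these genes turned with bintrafusp alfa: Ccr7 0.15, Penk 0.72, Ccl1 0.71, Tgfb1 0.20, Entpd1 -0.33, Ahr 0.37, Idi1 0.89, Cyp51 0.16, Tnfsf11 0.56, Csf1 -0.28 and Cxcr6 -0.086. Cluster 2 with anti-PD-L1 gave Pik3ap1 -0.16, Serpine2 -0.92, Igfbp7 0.15, Bmyc 0.47, Tgfb1 0.33, Tnfsf11 0.17 and Igkc -1.80. Cluster 2 with anti-TGF-β gave Spp1 -2.20, Serpine2 -1.11, Penk 2.02, Tgfb1 0.29, Mcm5 -0.041, Areg -0.46 and Entpd1 -0.15. Against anti-PD-L1 cluster 2 gave Cd274 -0.16 and Tgfbr2 -0.009. Against anti-TGF-β cluster 2 gave Gzmb -0.014 and Tnfsf11 0.18. Additivity in cluster 2 gave Rgcc -0.42, C2cd4b 2.02, Spp1 2.95, Ldlrad4 -0.18 and Mcm5 0.23.

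In cluster 3 alone these genes turned with bintrafusp alfa: Ccl1 1.054, Pdcd1 0.11, Cd274 -0.014, Tgfb1 0.18, Tcf7 1.71, Prdm1 -0.19, Tnfsf11 0.31, Icos -0.14, Fos -0.010, Alg9 -0.028 and Cxcr6 -0.063. Cluster 3 with anti-PD-L1 gave Cd74 0.22, Xcl1 0.45, Tgfb1 0.20, Itgae 1.43, Tcf7 1.78, Ifng -0.39, Gzmc 0.36, Havcr2 -0.15, Rora 0.33, Itga4 -0.15 and Igkc -0.82. Cluster 3 with anti-TGF-β gave Itgae 0.35 and Entpd1 -0.026. Against anti-PD-L1 cluster 3 gave Tcf7 -0.065. Against anti-TGF-β cluster 3 gave Ccl1 0.77 and Tnfsf11 1.10. Additivity in cluster 3 gave Ly6c2 -0.18 and Lag3 0.052.

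In cluster 5 alone these genes turned with bintrafusp alfa: Pdcd1 0.60, Tgfb1 0.038, Ly6c2 -0.62, Zbp1 -0.097, Cyp51 0.26, Slamf6 0.45 and Def8 0.21. Cluster 5 with anti-PD-L1 gave Cd74 0.088, Tgfb1 0.076, Foxp3 0.51, Gpr183 0.065, Rora 0.46, Nr4a3 0.26 and Ccl5 -0.18. Cluster 5 with anti-TGF-β gave Mcm5 -0.092 and Plac8 -0.35. Against anti-PD-L1 cluster 5 gave Pdcd1 0.059, Cd274 -0.088 and Igtp -0.14. Against anti-TGF-β cluster 5 gave Cd74 0.65, Pdcd1 0.059 and Idi1 0.31. Additivity in cluster 5 gave Ly6c2 -0.018.

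In cluster 6 alone these genes turned with bintrafusp alfa: Ccr2 -0.057, Cd274 -0.35, Tgfb1 0.12, Tcf7 0.53 and Entpd1 -0.37. Cluster 6 with anti-PD-L1 gave Serpine2 -0.12, Tgfb1 0.054, Smad7 0.13, Itgae 0.37, Gzmd 2.29, Gzmc 0.88, Entpd1 -0.013, Rora 0.13, Itga4 -0.29 and Ccl5 -0.026. Cluster 6 with anti-TGF-β gave Gzmd -0.56, Gzme -0.57, Plac8 -0.082 and Entpd1 -0.15. Against anti-PD-L1 cluster 6 gave Gzmd -2.51, Gzme -0.69, Tgfb1 0.070 and Ifng 0.044. Against anti-TGF-β cluster 6 gave Ccr2 -0.40, Cd274 -0.29, Itgae 0.33, Tcf7 0.10 and Gzmb -0.23. Additivity in cluster 6 gave Rgcc -0.61.

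Among clonotype tables, the 10 largest by TRB amino acid sequence alone held 16.3% in control, 13.3% with anti-TGF-β and 31.8% in bintrafusp alfa flow cell 2. Of clonotypes with both chains they held 17% in control, 18.7% in anti-PD-L1 flow cell 1, 13.2% with anti-TGF-β, and 32.5% and 32.2% with bintrafusp alfa. Counted by cells, the effective number of V segments differed from control by -1.28 with anti-PD-L1 and -1.97 with anti-TGF-β.

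Flow cell numbers do not pair the samples by the check made here: correlations of captures with the same number, after group means were removed, lay between -0.0549 and 0.124. With the flow cell as a block, 88 of 95 list calls were made again, and with an estimated correlation 0. Effective numbers of V segments, which differed from control by 0.54, 0.73 and -2.79 with anti-PD-L1, anti-TGF-β and bintrafusp alfa, had 1 exact permutation p over all 4 groups, 0.0833 within flow cells.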

Other observations

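Cdk5rap1, which modifies mitochondrial transfer RNA, rose with anti-TGF-β in each class tested: 1.54 ± 0.098 in CD8-like, 1.55 ± 0.16 in conventional CD4-like and 1.69 ± 0.12 in regulatory T-like cells (log2 fold change with SE, edgeR, n = 2 per group). It also rose with anti-PD-L1 in CD8-like cells (1.16 ± 0.091), and with bintrafusp alfa by 0.42 ± 0.093, 0.73 ± 0.17 and 0.95 ± 0.20 in these classes, the last pair not passing in thinned cells. In CD8-like cells it was lower with bintrafusp alfa than with anti-TGF-β (-1.12 ± 0.081), by -0.051 and -0.07 in clusters 1 and 6 alone, which did not pass. Def8, a regulator of lysosome position, fell with bintrafusp alfa in the same classes: -1.87 ± 0.081, -2.19 ± 0.27 and -3.34 ± 0.32. In CD8-like cluster 5 alone Def8 stood at 0.21 and did not pass. Each treatment was 1 pool of mice, so a difference between mice in these genes was not tested apart from treatment.

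Cluster 9, left without a class, is led by Foxp3, Frmd5 and Areg, a growth factor of tissue-repairing regulatory T cells, and has a median of 12324 UMIs per cell. It made up 2.97% of cells in control, 2.17% with anti-PD-L1, 7.10% with anti-TGF-β and 1.19% with bintrafusp alfa, and its cells are not counted as regulatory T-like here.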
